A study of Mus musculus with 18 samples.

How the data were processed

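RNA of whole lung of C57BL/6 mice was measured on 18 single-colour oligonucleotide arrays of 1 type, hybridised with biotin-labelled cRNA. Per the labels, 3 arrays came from animals given saline and 3 from each of 5 times after bleomycin, from 7 days to 4 months, and the 3 arrays of a group are biological replicates. Bleomycin had been instilled into the trachea at 0.10 U/10 g of body weight in 50 μl of saline. It is not stated whether an array holds RNA of a single mouse or of a pool. The time at which the saline animals were killed is not given, so time since instillation and treatment cannot be told apart in the comparisons against saline.

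Each deposited array file held a raw and a normalized column of spot intensity for 20287 features, of which 19799 were discovery probes and the others controls. Negative raw values show that the authors' software had already subtracted the local background. The normalized column was the raw column divided by 1 constant for each array, the median of its discovery probes. The table of all samples that the authors deposited holds the same normalized intensity for every array, digit for digit. In both columns of the deposited files, values with 3 or 4 decimals had lost their decimal point, which touched 92.26% of the raw and 48.58% of the normalized cells. The points were restored from the fixed ratio of the 2 columns on each array. Of 365166 spots, 1075 were missing, 221316 were settled by that ratio, 96901 by rounding and 14651 by the signal strength column. The remaining 31223 stayed open and were taken at the smaller of the values that fitted, that with 4 decimals, except 20 moved to the larger by comparison with the other arrays. On simulated files, built from the restored values under the method's own assumptions, 223 of 364091 values (0.0612%) came back wrong. That share is not an error rate of the deposited files.

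Log2 intensities were computed with limma 3.58.1 in R 4.3.3. The raw column was corrected by the normexp model with an offset of 50 and quantile normalized between arrays. This model expects separate foreground and background columns, and was applied here to a column already subtracted. Spots marked as contaminated, irregular or masked were set to missing, between 56 and 92 discovery probes on an array, and saturated spots (9 to 40) were kept. A further mark, the letter P on 0 to 21 discovery probes of an array, is not explained by the files. Probes above background on at least 3 of the 18 arrays were kept, 13724 of 19799, of which 12877 carried 1 gene symbol (11554 genes). Between 13696 and 13724 of them could be tested in a comparison.

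A linear model with 6 group means was fitted by limma to all 18 arrays, with the empirical Bayes variance. Comparisons were contrasts of group means, two-sided, and a probe was called at a Benjamini-Hochberg adjusted p under 0.05 over all probes tested. Following the stages the labels name, 1 and 2 months were averaged as fibrotic and 3 and 4 months as reversion, with 7 days as inflammatory. The number of arrays limits the precision. In 10 simulations with the spread of 17 arrays and 200 changed probes, changes of log2 1 were called for 65.8% of probes at 7 days, 75.8% in the fibrotic comparison and 87.9% between reversion and fibrotic. At log2 2 these shares were 92.5%, 96.9% and 98.2%. False calls made up 5.38%, 6.19% and 5.68% of all calls. The array left out of that spread, 4 months replicate 1, widens it in the fit to all 18 arrays. These shares therefore do not describe the calls of that fit. At 7 days against saline 206 probes were called with that array and 1502 without it.

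Gene lists were fixed before the data were examined: 18 of pathways and technical markers and 16 of cell types. A list entered with the brightest kept probe of each gene, and 33 of 34 lists had enough measured genes for a test. Each was tested against all other genes by camera with a preset correlation of 0.01, adjusted over the lists of a comparison. The same test was run with an estimated correlation, and fry was run beside it. Members were counted as risen or fallen over all probes and adjusted over the list alone. With simulated independent genes, a list shifted by 0.5 was called in 10 of 10 simulations by both camera tests, and other lists in 1 of 310 tests with the preset and 0 of 310 with the estimated correlation. On the real arrays the estimated correlation was 0.351 for matrix proteins and 0.867 for alveolar type 1 cells. The simulated rates therefore do not describe the measured lists. A list of 30 hepatocyte markers, 17 of them measured, was added after the values had been seen.

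Genes to name were set by a rule fixed before the data were examined. In 4 comparisons (7 days, fibrotic and reversion each against saline, and reversion against fibrotic), it took the 10 largest rises and the 10 largest falls among called genes in which every array of the first group lay on the same side of the mean of the second. Where no gene was called, it took the 5 with the smallest p. It added up to 4 called genes of each list and 15 genes always looked up: Col1a1, Col3a1, Fn1, Tnc, Eln, Timp1, Mmp12, Mmp19, Spp1, Acta2, Tgfb1, Cdkn1a, Sftpc, Ager and Scgb1a1. Fn1 had no probe on the array, and 1 gene that the rule selected is not reported here. Sftpc and Scgb1a1 were saturated on all 17 arrays other than 4 months replicate 1, so no fold is given for them. A probe below background on all arrays of a group is given as at least N-fold, measured against the background level.

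Alternatives fixed before the data were examined were no background correction, median scaling, no filter or a stricter filter, only the compared groups, trend and robust variance, the replicate number as a replicate block, array series as a block or alone, the authors' normalized values, and leaving out each array. Added after seeing the data were fits without 4 months replicate 1 and without that array and saline replicate 1, list tests without these arrays, also with an estimated correlation, an offset of 10, and treating as missing the values whose decimal point stayed open. Array series were read from the serial numbers of the slides: 12 arrays (series A) hold all saline and 7 days arrays, and 6 (series B) hold only bleomycin arrays from 1 month on. What the series stand for is not stated. The series block was fitted only with all 18 arrays. It therefore rests in part on 4 months replicate 1, the only series A array at 4 months. All 18 arrays stay in the values reported as fixed, and those without the doubted arrays stand beside them.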

Results

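Whole-lung RNA of C57BL/6 mice was measured on 18 arrays: 3 from animals given saline and 3 from each of 5 times after intratracheal bleomycin, a DNA-cleaving drug that injures the lung and is used to bring about pulmonary fibrosis in mice. The labels call 7 days the inflammatory stage, 1 and 2 months the fibrotic stage and 3 and 4 months the reversion stage. Between 11548 and 12983 of 19799 discovery probes lay above background on 17 of the arrays, and 8746 on 4 months replicate 1. The median raw intensity was 27.8 on that array and between 69.5 and 109.1 on the others. On the same array the median of 17 measured hepatocyte markers lay 7.38 log2 above that of the other arrays, and the median of the alveolar type 2 cell list lay at -5.004. On saline replicate 1 the thymus and lymph node list lay 2.89 log2 above the other arrays and the cell cycle list 1.43 above. Both arrays remain in the values below, and probe counts and list results that change without them are given beside.

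**Figure D1:**
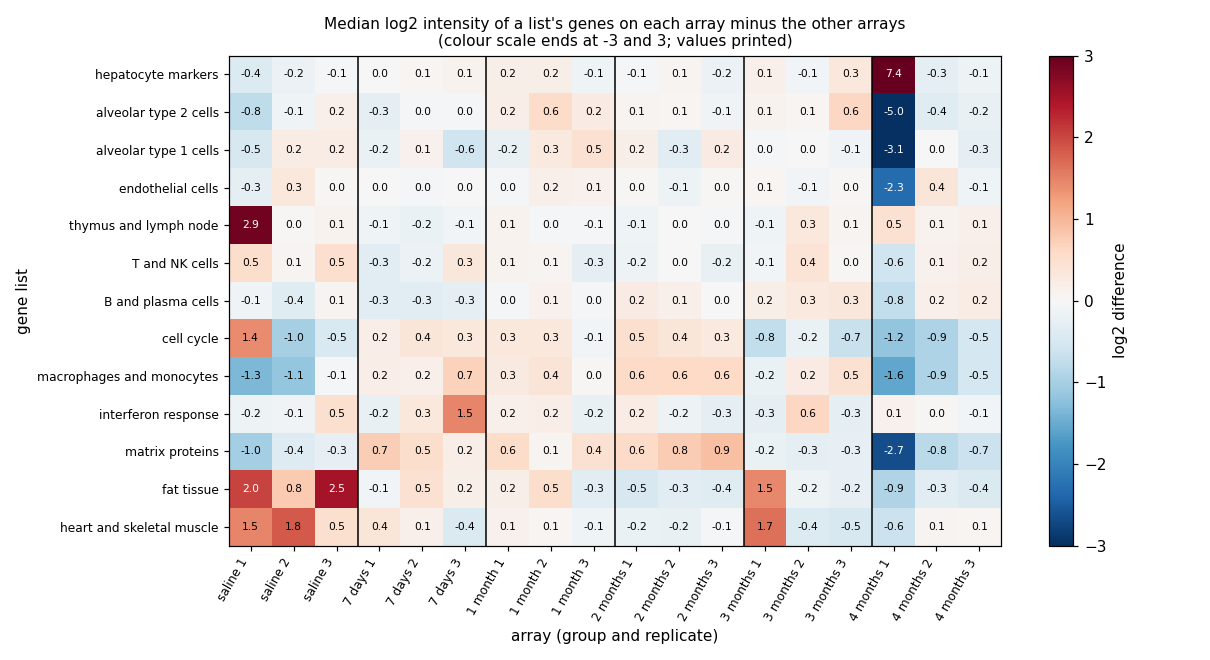
Median log2 intensity of the genes of 13 lists on each of the 18 arrays minus the median of the other arrays; columns are arrays by group and replicate, and the colour scale ends at 3 log2 either way. The hepatocyte markers stand at 7.38 on 4 months replicate 1, and the thymus and lymph node list at 2.89 on saline replicate 1.

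The first comparison asked which transcripts differed 7 days after bleomycin. Spp1, the secreted matrix protein osteopontin, went from a log2 intensity of 9.51 ± 1.56 (SD, n = 3) on saline to 14.26 ± 0.48 (SD, n = 3), a 27.0-fold rise. Timp1, an inhibitor of matrix metalloproteinases, rose 22.1-fold, from 8.42 ± 0.89 to 12.89 ± 0.35. Cdkn1a, the p53 target that encodes the cell cycle inhibitor p21, rose 9.48-fold, from 8.87 ± 0.43 to 12.11 ± 0.36. Col1a1, a chain of type I collagen, rose 4.39-fold (log2 2.14, SE 0.40, adjusted p = 0.0197).

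Among the other genes with the largest rises were the serine protease inhibitors Serpina3n (log2 3.68) and Serpina3b (3.08) and Sprr1a (3.56), a cornified envelope protein of stressed epithelia. Ccl7, a chemokine that attracts monocytes, rose by log2 3.37, and Tgfbi, a matrix protein induced by TGF-beta, by 3.04. The neutrophil genes Mmp8 (3.07), a collagenase, and Cd177 (3.05), a surface protein, rose as well. Ccl7, Cd177 and Sprr1a were above background on only 1 or 2 of the 3 saline arrays. The falls were smaller. Tff2, a secreted peptide of mucous epithelia, was at least 3.50-fold lower and below background on all 7 days arrays. Cyp4a12b, a fatty acid hydroxylase, fell by 1.81, Chad, a cartilage matrix protein, by 1.69, and Cytip, an adaptor of lymphocyte adhesion, by 1.47. Cyp1a1, a xenobiotic-metabolising enzyme, fell by 1.23 and Spns2, the transporter of sphingosine 1-phosphate, by 1.10, while its other probe had the opposite sign. Mapk1ip1 (-1.30), Patz1 (-1.20), Med13l (-0.93) and the proton pump subunit Atp6v1b1 (-0.91) completed the 10 largest falls. Several genes looked up in advance did not pass the test: Tnc, the matrix glycoprotein tenascin C, at log2 2.44 (adjusted p = 0.0912), Mmp12, macrophage elastase, at 1.95 (0.182), Mmp19 at 1.44 (0.141), Col3a1 at 1.16 (0.377, saturated on 2 of the 3 arrays at 7 days), Acta2 at 0.61 (0.672), Tgfb1 at 0.36 (0.681) and Ager at -0.12 (0.976). Eln, below background on all saline arrays, was at least 1.13-fold higher and did not pass either (0.173).

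At 7 days, 5 of 36 matrix protein genes rose and 0 fell (15 rose adjusted over the list alone), among them Vcan, a proteoglycan, by log2 2.58 and Ccn4, a matricellular protein, by 1.40. The mean of the list was 1.00 (camera adjusted p = 1.74e-09, and adjusted p = 0.213 with an estimated correlation). Matrix proteases and inhibitors had 5 of 26 risen (10 adjusted over the list alone), with Mmp14 at 1.71 and the lysosomal protease Ctsd at 1.52, and a mean of 0.97 (4.26e-07, and adjusted p = 0.197 with an estimated correlation). Matrix assembly enzymes had 0 of 16 risen (9 risen and 1 fallen adjusted over the list alone), at a mean of 0.70 (8.59e-05, and adjusted p = 0.208 with an estimated correlation). Coagulation and fibrinolysis had 1 of 16 risen, the plasminogen activator Plat at 1.39 (8 adjusted over the list alone), at a mean of 0.82 (0.000358, and adjusted p = 0.103 with an estimated correlation). The members risen over all probes in these 4 lists, in this order, numbered 20, 11, 9 and 7 without 4 months replicate 1 (23, 14, 12 and 10 adjusted over the list alone).

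The macrophage and monocyte list had 7 of 26 genes risen at 7 days (12 risen and 1 fallen adjusted over the list alone) at a mean of 1.00 (camera adjusted p = 1.97e-07, and adjusted p = 0.197 with an estimated correlation). Its largest named rises were the scavenger receptor Msr1 (2.11), the Fc receptor Fcgr3 (1.91) and Gpnmb (1.73), a glycoprotein of lipid-laden macrophages. Adgre1, which encodes F4/80, was at least 2.02-fold higher, being below background on all saline arrays. The list of alternatively activated macrophages had 2 of 16 risen (4 adjusted over the list alone), Spp1 and the interleukin 4 receptor chain Il4ra (1.10), at a mean of 1.30 (0.000253, and adjusted p = 0.197 with an estimated correlation). Complement had 3 of 16 risen (4 adjusted over the list alone), namely C3ar1 (2.87), C1qa (2.18) and C1qc (1.94), at a mean of 0.85 (8.59e-05, and adjusted p = 0.248 with an estimated correlation). Of 23 p53 response genes 6 rose (9 risen and 1 fallen adjusted over the list alone), including Gdf15 (1.82), Ccng1 (1.45) and the apoptosis effector Bax (1.40), at a mean of 0.65 (1.3e-05, and adjusted p = 0.0582 with an estimated correlation). Chemokines and cytokines had 2 of 41 risen (5 adjusted over the list alone), Ccl7 and Cxcl12 (1.88), and neutrophils 1 of 13 (3 adjusted over the list alone). Their means were 0.67 (0.0109) and 0.56 (0.0109), with adjusted p = 0.632 and adjusted p = 0.464 with an estimated correlation. The NRF2 and oxidative stress list had 2 of 20 risen (5 adjusted over the list alone), Gsr (1.40) and Sod3 (1.27), at a mean of 0.51, and the interferon response list 0 of 27 (1 adjusted over the list alone) at 0.42. Their camera adjusted p were 0.00755 and 0.0321, and adjusted p = 0.427 and adjusted p = 0.717 with an estimated correlation. In these 8 lists, in this order, the members risen over all probes numbered 14, 6, 4, 9, 7, 3, 7 and 1 without 4 months replicate 1, and 1 p53 response gene fell. The interferon list stood at 1.46 above the other arrays on 7 days replicate 3 but at -0.216 on 7 days replicate 1. It no longer passed without 4 months replicate 1 (adjusted p = 0.057). When saline replicate 1 was left out as well, 4 of these lists did not pass: chemokines and cytokines (mean 0.56, adjusted p = 0.236), neutrophils (0.38, 0.193), NRF2 and oxidative stress (0.40, 0.104) and the interferon response (0.30, 0.318).

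Of the lists with a lower mean at 7 days, 4 passed at the preset correlation, all with 0 members fallen over all probes. They were heart and skeletal muscle (mean -1.42, 0 of 19 fallen adjusted over the list alone), fat tissue (-1.28, 3 of 12, while 1 rose), T and NK cells (-0.83, 0 of 25) and thymus and lymph node (-1.03, 0 of 7). Their camera adjusted p were 4.58e-06, 0.00062, 5.45e-05 and 0.00903, and adjusted p = 0.312, 0.197, 0.213 and 0.427 with an estimated correlation. Without both 4 months replicate 1 and saline replicate 1 the thymus and lymph node mean was -0.11 (0.361) and that of T and NK cells -0.36 (0.00703). The cell cycle list had 0 of 41 genes called and a mean of 0.18 (adjusted p = 0.41), and a mean of 0.89 (5.94e-12, and adjusted p = 0.396 with an estimated correlation) without the same 2 arrays. Fat tissue had 7 of 12 genes fallen adjusted over the list alone (3 over all probes, 1 risen) when 4 months replicate 1 was left out, and muscle and thymus 1 each. Club and goblet cells did not pass over all 18 arrays but were lower without 4 months replicate 1 (-0.63, 0.0088) and without both (-0.95, 0.00227), as were alveolar type 1 cells without both (-0.49, 0.0107). These had adjusted p = 0.374 and 0.576 with an estimated correlation without both, and T and NK cells adjusted p = 0.578. Fst (at least 2.65-fold higher), Cald1 (log2 1.90, while its other probe had the opposite sign) and the platelet chemokine Pf4 (1.72) rose within lists that did not pass as a whole: TGF-beta pathway (2 of 26 risen, 3 adjusted over the list alone, mean 0.23), contractile and fibroblast genes (1 of 19, 1 adjusted over the list alone, mean 0.07, while the test pointed lower) and red cells and platelets (1 of 7, mean 0.23).

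By limma, 206 of 13696 probes were called at 7 days, 179 higher and 27 lower, and 2361 had an unadjusted p under 0.05. Without 4 months replicate 1, which widens the spread shared by all groups, 1502 were called (962 higher, 540 lower), and 2104 without saline replicate 1 as well. The count also rested on single arrays of the groups compared: it was 131 without saline replicate 1, 24 without saline replicate 2, 8 without 7 days replicate 1, 124 without 7 days replicate 2 and 37 without 7 days replicate 3. All arrays of this comparison belong to array series A (792 probes within it), the replicate block gave 207 and the array series as a block 221. Median scaling gave 336, and 132 were called with open decimals set to missing.

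**Figure D2:**
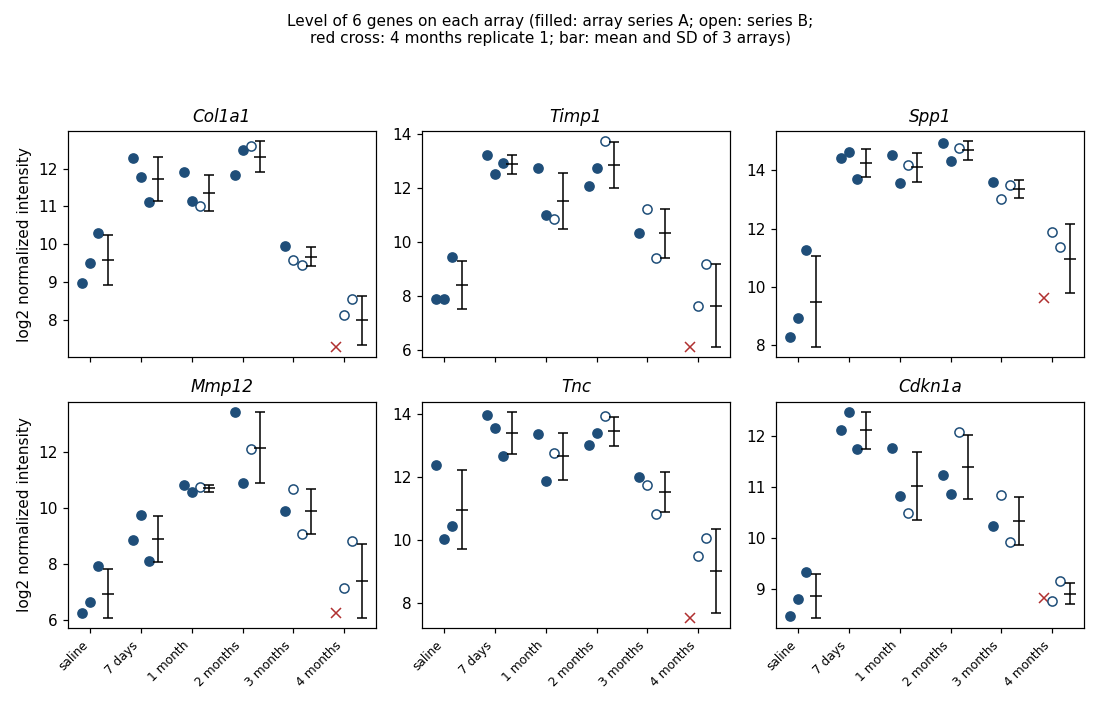
Log2 normalized intensity of Col1a1, Timp1, Spp1, Mmp12, Tnc and Cdkn1a on each array by group, with the mean and SD of 3 arrays; filled points are array series A, open points series B and the cross is 4 months replicate 1. Mean Spp1 stood at 9.51 on saline, 14.26 at 7 days, 14.68 at 2 months and 10.97 at 4 months.

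The comparison of 1 and 2 months with saline asked what marks the fibrotic stage. Spp1 rose 29.6-fold, to 14.40 ± 0.49 (SD, n = 6) from 9.51 ± 1.56 (SD, n = 3). Ighg1, an immunoglobulin G heavy chain whose family members share near-identical sequence, rose 29.2-fold to 11.47 ± 0.89, and Mmp12 22.2-fold to 11.43 ± 1.12; both were above background on 1 of the 3 saline arrays. Timp1 rose 13.6-fold, Cdkn1a 5.08-fold and Col1a1 4.75-fold (log2 2.25, SE 0.35, adjusted p = 0.00395).

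Clec4n, the macrophage lectin dectin 2, rose by log2 3.62, the metalloproteinase Adam19 by 3.25 and Rspo1, an agonist of Wnt signalling, by 3.19. Further large rises were those of Cd177 (2.89), the matricellular gene Thbs4 (2.84) and Serpina3n (2.81). The metalloproteinase Mmp19 rose by 1.72, and Eln, elastin, was at least 1.25-fold higher. The largest falls were those of Adipoq, the fat cell hormone adiponectin (-2.89), Cox8b, a muscle and brown fat subunit of cytochrome c oxidase (-2.86), Vta1, of endosomal sorting (-2.68), Retn, the fat cell hormone resistin (-2.33), and Tgfbr3, a co-receptor of TGF-beta (-2.33), for which 2 other probes had the opposite sign. The muscle gene Smpx (-2.31), the fatty acid carrier Fabp4 (-2.13), Glcci1 (-2.11, the other probe of opposite sign), Tff2 (-2.10) and the potassium channel Kcnq1 (-2.09) followed. Smpx and Tff2 were above background on 1 of the 6 fibrotic arrays. The fat tissue list was highest on saline replicates 3 and 1, at 2.49 and 2.03 log2 above the other arrays. That of heart and skeletal muscle was highest on saline replicate 2 and 3 months replicate 1, at 1.84 and 1.66. The cause of the falls of fat and muscle genes was not tested. Tnc stood at log2 2.10 (adjusted p = 0.0558), Col3a1 at 1.17 (0.232), Tgfb1 at 0.68 (0.216), Acta2 at 0.68 (0.479) and Ager at 0.58 (0.785), none of which passed. Col3a1 was saturated on 5 of the 6 fibrotic arrays.

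Matrix proteins had 11 of 36 genes risen and 0 fallen (19 risen adjusted over the list alone), with Col5a1 at log2 1.69 and Thbs2 at least 1.78-fold higher. The mean was 1.12 (camera adjusted p = 7.36e-12, and adjusted p = 0.196 with an estimated correlation). Matrix proteases and inhibitors had 11 of 26 risen (13 adjusted over the list alone), with the cathepsins Ctsd (2.19) and Ctsb (1.40) and the membrane protease Mmp14 (1.76), at a mean of 1.19. Matrix assembly enzymes had 3 of 16 risen (11 risen and 1 fallen adjusted over the list alone), the procollagen protease Adamts2 (1.46), the cross-linking enzyme Loxl3 (1.00) and the lysyl hydroxylase Plod3 (0.94), at a mean of 0.73. Their camera adjusted p were 4.83e-09 and 7.33e-05, and both had an adjusted p = 0.196 with an estimated correlation. Coagulation and fibrinolysis had 3 of 16 risen (4 adjusted over the list alone), F7 (1.80), Plat (1.10) and Anxa2 (0.88), at a mean of 0.69 (0.00467, and adjusted p = 0.196 with an estimated correlation). The members risen over all probes in these 4 lists, in this order, were 27, 15, 11 and 8 with 4 months replicate 1 left out, and 1 matrix assembly gene fell.

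Macrophages and monocytes had 7 of 26 genes risen and 1 fallen (16 and 1 adjusted over the list alone), with Gpnmb at 2.69, Cd68, a lysosomal glycoprotein, at 2.30, Fcgr3 at 2.04 and the growth factor receptor Csf1r at 1.23. The list mean was 1.02 (camera adjusted p = 1.04e-07, and adjusted p = 0.196 with an estimated correlation). Alternatively activated macrophages had 2 of 16 risen (4 adjusted over the list alone), Spp1 and Il4ra (1.24), and complement 4 of 16 (4 adjusted over the list alone), C1qa (2.30), C3ar1 (2.17), C1qc (1.82) and C1qb (1.79). The means of these lists were 1.17 (0.000776) and 0.77 (0.000333), with adjusted p = 0.196 and adjusted p = 0.289 with an estimated correlation. Chemokines and cytokines had 3 of 41 risen (5 adjusted over the list alone), Cxcl12 (1.47), Cxcl16 (1.28) and Ccl3 (1.16), at a mean of 0.49 (0.0245, and adjusted p = 0.746 with an estimated correlation). The p53 response list had 4 risen and 1 fallen of 23 (9 and 1 adjusted over the list alone). Bax rose by 1.26 and the sestrin Sesn2 by 0.68, while Sesn1 fell by 0.99, and the mean was 0.33 (0.0303, and adjusted p = 0.206 with an estimated correlation). Leaving out 4 months replicate 1 gave 15, 8, 5, 9 and 10 members risen over all probes in these 5 lists, in this order, with 1 fallen macrophage gene and 2 fallen p53 response genes. The p53 response list did not pass without 4 months replicate 1 (0.0593) or with saline replicate 1 left out as well (mean 0.28, 0.189), nor did chemokines and cytokines pass with both left out (0.37, 0.282). With array series as a block neither of these lists passed.

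Fat tissue had 5 of 12 genes fallen (6 adjusted over the list alone), among them Cidea (-1.39), at a mean of -1.63, and heart and skeletal muscle 0 of 19 (0 adjusted over the list alone) at -1.64. Camera gave adjusted p of 2.35e-05 and 7.82e-07, and adjusted p = 0.196 and adjusted p = 0.281 with an estimated correlation. Leaving out 4 months replicate 1 gave 7 of 12 fallen in the fat list and 6 of 19 in the muscle list (7 and 15 adjusted over the list alone). On single arrays the fat list stood at 2.03, 0.79 and 2.49 log2 above the other arrays on saline replicates 1, 2 and 3, at 1.45 on 3 months replicate 1 and at no more than 0.53 on the remaining arrays. The muscle list stood at 1.46, 1.84, 0.48 and 1.66 on the same 4 arrays. T and NK cells (mean -0.86, 0 of 25 fallen), thymus and lymph node (-1.02, 0 of 7) and club and goblet cells (-0.68, 0 of 13, 1 fallen adjusted over the list alone) passed at 2.35e-05, 0.019 and 0.0427, and had adjusted p = 0.201, 0.494 and 0.523 with an estimated correlation. Without 4 months replicate 1 and saline replicate 1 the thymus and lymph node mean was -0.05 (0.834), that of T and NK cells -0.38 (0.00826) and that of club and goblet cells -1.08 (0.000832), and the cell cycle list went from 0.19 (0 of 41 called, 0.415) to 0.90 (2.61e-11, and adjusted p = 0.434 with an estimated correlation). Over all probes 4 T and NK cell genes, 4 club and goblet cell genes and 1 thymus gene fell when 4 months replicate 1 was left out. The ciliated cell list, which did not pass over all 18 arrays, was lower without both (-0.36, 0.0261). Without both, T and NK cells, club and goblet cells and ciliated cells had adjusted p = 0.712, 0.339 and 0.539 with an estimated correlation.

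The other lists did not pass in the fibrotic comparison, though some of their genes did. Means and adjusted p were 0.08 and 0.93 for contractile and fibroblast genes, 0.17 and 0.407 for the TGF-beta pathway, -0.14 and 0.407 for the interferon response, 0.45 and 0.377 for MHC class II, 0.27 and 0.377 for NRF2 and oxidative stress, 0.13 and 0.235 for developmental signalling, and 0.07 and 0.93 for immediate early and heat shock genes. They were 0.08 and 0.957 for lipid and surfactant metabolism (the test pointed lower), -0.45 and 0.139 for the circadian clock, 0.46 and 0.111 for alveolar type 2 cells, 0.01 and 0.883 for alveolar type 1 cells (the test pointed lower), -0.17 and 0.428 for ciliated cells and 0.03 and 0.815 for endothelial cells. For neutrophils they were 0.26 and 0.235, for B and plasma cells 0.50 and 0.103, for mast cells and eosinophils -0.07 and 0.559, for red cells and platelets 0.19 and 0.478, and for mesothelium 0.16 and 0.761. The Y-linked and Xist list had 4 measured genes, 0 of them called, and no set test. The Y-linked genes Eif2s3y and Ddx3y were not above background on saline replicate 3, 7 days replicate 1, 3 months replicate 3 and 4 months replicates 1 and 3. Eif2s3y stood there at 5.88, 5.85, 7.035, 5.97 and 6.04. Its value was missing on 1 month replicate 3, 2 months replicate 3 and 3 months replicate 2. On the last of these Ddx3y was not above background. Eif2s3y stood at 8.39 and 9.03 on saline replicates 1 and 2, 8.86 and 8.76 on 7 days replicates 2 and 3, and 9.47 on 4 months replicate 2. Arrays of a group may thus differ in sex, which was not part of the model. Within these lists the antioxidant genes Hmox1 (1.95) and Sod3 (1.46), Tgfbi (1.87), the Wnt inhibitor Sfrp1 (1.82 on the brighter of 2 called probes), Mmp8 (2.27), the type 2 cell protease Ctsh (1.25), Atf3 (1.13), Pf4 (1.11) and Id1 (0.92) rose. Fst was at least 1.87-fold and the Wnt receptor Fzd2 at least 1.33-fold higher. The fatty acid elongase Elovl6 (-1.53) and Gsta4 (-0.98) fell, and the clock output gene Hlf was at least 1.35-fold lower.

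**Figure D3:**
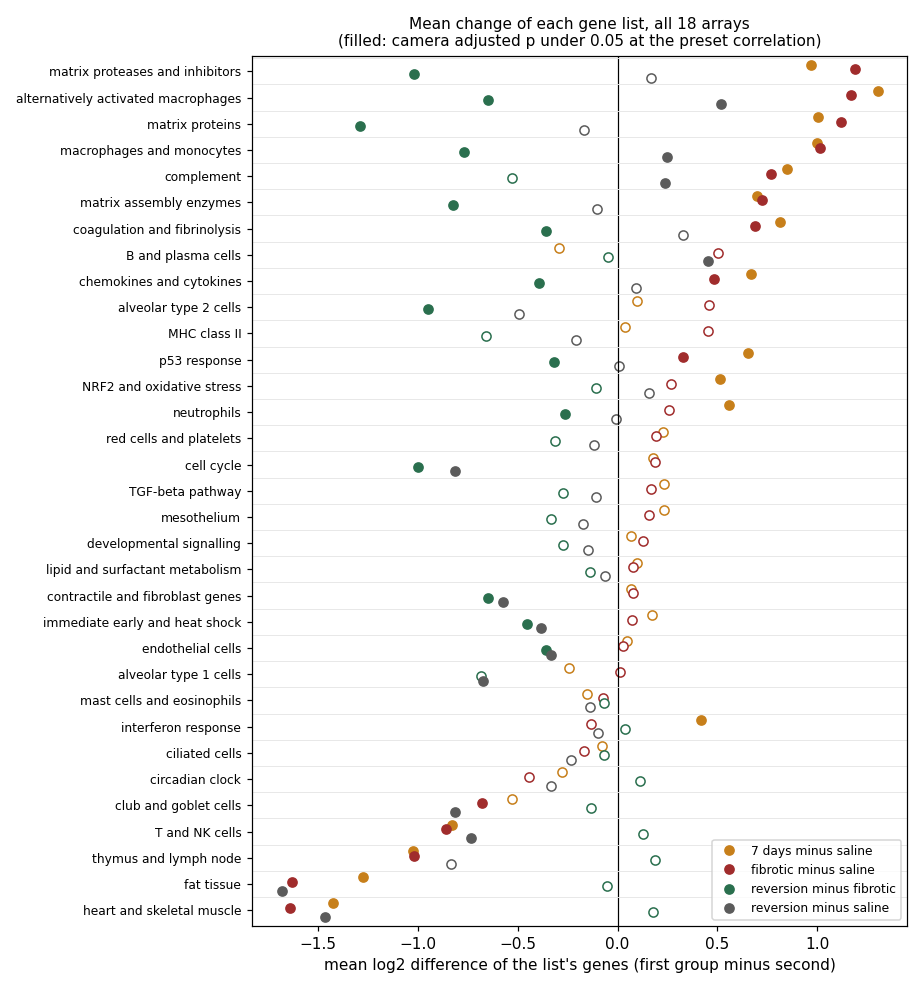
Mean log2 difference of the genes of each of 33 lists in 4 comparisons over all 18 arrays; each point is 1 list in 1 comparison, filled where the camera adjusted p at the preset correlation was under 0.05. Matrix proteins stood at 1.00 at 7 days, 1.12 in the fibrotic comparison and -1.29 between reversion and fibrotic.

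By limma, 561 of 13696 probes were called between the fibrotic stage and saline, 431 higher and 130 lower. The count was 2837 (1591 higher, 1246 lower) without 4 months replicate 1, 3218 without saline replicate 1 as well, 114 without saline replicate 2, 357 without saline replicate 3, 252 without 1 month replicate 1 and 298 without 2 months replicate 3. Within array series A it was 1244, with the series as a block 566, with the replicate block 537 and with only the compared groups in the fit 1772.

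Taken alone, 1 month against saline gave 43 called probes (34 higher, 9 lower) and 2 months against saline 518 (416 higher, 102 lower). These were 922 and 2591 without 4 months replicate 1. Median scaling changed the 1 month split to 90 higher and 10 lower among 100 called. At 1 month the count was 9 without saline replicate 1, 6 without saline replicate 2, 89 without saline replicate 3, 0 without 1 month replicate 1, 0 without 1 month replicate 2 and 10 without 1 month replicate 3; at 2 months it was 120 without saline replicate 2 and 105 without 2 months replicate 3. The replicate block gave 43 and 500, the array series as a block 24 and 507, and series A alone 196 and 444. The direct test of 2 months against 1 month called 0 probes by limma (209 at an unadjusted p under 0.05), 0 also without 4 months replicate 1, 0 with the replicate block, 0 with the array series as a block, 0 within series A and 2 within series B, where each of these months has 1 array and the spread comes from other groups.

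The comparison of the fibrotic stage with 7 days asked what separates fibrosis from the earlier inflammation. The list with antibody genes had the smallest p of the comparison. Ighg1 was below background on all 3 arrays at 7 days, at 6.08 ± 0.22 (SD, n = 3), and stood at 11.31 ± 1.29 at 1 month and 11.63 ± 0.46 at 2 months (adjusted p = 0.0633, not called). The B and plasma cell list had 0 of 21 genes risen over all probes (2 adjusted over the list alone, and 2 and 6 without 4 months replicate 1) and a mean of 0.80 (camera adjusted p = 1.59e-07, and adjusted p = 0.341 with an estimated correlation). The MHC class II list had 0 of 9 risen at a mean of 0.42 (0.0355, and adjusted p = 0.983 with an estimated correlation), and did not pass without 4 months replicate 1 (0.061) or with array series as a block (0.119), but did with saline replicate 1 left out as well (0.0307). Alveolar type 1 (mean 0.26) and type 2 cells (0.36) did not pass over all 18 arrays, at 0.226 and 0.211, but did with 4 months replicate 1 left out, at 0.0027 and 0.0118. They passed with both arrays left out too, at 0.00113 and 0.00361. Neutrophils (-0.30, 0.0658 over all 18 arrays) passed with 4 months replicate 1 left out (0.047), with array series as a block and with the mean of all probes of a gene, but not with both arrays left out (0.061). Each of these 3 lists had an adjusted p = 0.99 with an estimated correlation without the arrays. The lists of the interferon response (0 of 27 fallen, mean -0.55), p53 response (0 of 23, 2 fallen adjusted over the list alone, mean -0.33) and NRF2 and oxidative stress (0 of 20, mean -0.25) were lower in the fibrotic stage than at 7 days, at camera adjusted p of 6.86e-07, 2.14e-05 and 0.0127. With an estimated correlation these had adjusted p = 0.983, 0.058 and 0.983, and NRF2 and oxidative stress did not pass with array series as a block (0.119). The interferon difference rested on 1 array. The interferon list mean was 10.12 on 7 days replicate 3, 8.37 and 8.89 on the others at 7 days and between 8.30 and 8.81 on the fibrotic arrays. The NRF2 and oxidative stress list was highest of all arrays on 7 days replicate 1, at 0.75 log2 above the other arrays.

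No single probe was called between the fibrotic stage and 7 days: limma gave 0, with 830 at an unadjusted p under 0.05, 11 without 4 months replicate 1, 2 without 7 days replicate 2, 0 with the replicate block, 0 with the array series as a block and 1 within series A. Calls against saline overlapped between both stages. Of the probes called at 7 days and in the fibrotic comparison, 138 were higher in both (5.63 if the calls were independent) and 20 lower in both (0.256 if independent), and 0 had opposite signs. Across probes the log2 differences had a covariance of 0.232, against 0.073 for simulated unchanged groups sharing 3 saline arrays. Without 4 months replicate 1 these were 0.232 and 0.036. The simulation gave all groups the same spread for a probe, so variation particular to the saline arrays was not in it. Its value is therefore not the part due to the shared arrays. Probes are not independent replicates, and the 3 saline arrays were not divided between the comparisons, since that would leave 1 comparison with a single control.

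The comparison of 3 and 4 months with 1 and 2 months asked which of these changes reverted. Col1a1 fell from 11.84 ± 0.66 (SD, n = 6) to 8.83 ± 1.02 (SD, n = 6), an 8.02-fold fall (log2 -3.004, SE 0.28, adjusted p = 0.000344). Timp1 fell by log2 3.20, Tnc by 2.78, Mmp12 by 2.78, Spp1 by 2.23, Col3a1 by 1.93 (saturated on 5 of the 6 fibrotic arrays, which compresses the difference), Cdkn1a by 1.59, Acta2, smooth muscle actin, by 1.43 and the cytokine Tgfb1 by 1.00. Eln was at least 1.30-fold lower and below background on all 6 reversion arrays. These arrays include 4 months replicate 1, on which the median of the matrix protein list lay 2.66 log2 below the other arrays. The mean of that list between reversion and fibrotic was -1.29 with 4 months replicate 1 and -1.04 without it. The falls above include that array, and their sizes can be overstated by it.

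Adam19 (-2.93), Thbs4 (-2.89), Rspo1 (-2.84), the glycolytic enzyme Pkm (-2.49), Col1a2, the other chain of type I collagen (-2.48), and Clec4n (-2.38) were the remaining largest falls. These falls, too, include 4 months replicate 1, which can overstate their sizes. The largest rise was that of Fabp1, a fatty acid carrier of liver and gut, by 3.25 on all 18 arrays and 2.62 without 4 months replicate 1. Vta1 rose by 2.14, the paraoxonase Pon1 by 1.99, the fatty acid hydroxylase Cyp4f15 by 1.73, the lysine-degrading enzyme Aass by 1.67, Nrn1 by 1.60, Nadsyn1, of NAD synthesis, by 1.49, the glutathione transferase Gsta3 by 1.39 and the synaptic gene Rims2 by 1.37. Without 4 months replicate 1 the rises of Pon1, Cyp4f15, Aass and Gsta3 were 1.80, 1.23, 1.23 and 0.89, and all passed the test. Pxmp2, a peroxisomal membrane protein, rose by 1.69 with values on only 2 of the 6 reversion arrays. These were 3 months replicate 1 and 4 months replicate 1, so its rise could not be tested without the latter. Mmp19 stood at -0.90 (adjusted p = 0.101) and Ager at -1.94 (0.149); without 4 months replicate 1 both passed, at -1.24 (0.00171) and -0.86 (0.0029).

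Of 36 matrix protein genes 25 fell and 0 rose (29 fell adjusted over the list alone), with Col5a1 at -2.08 and Col4a2 at -2.04. The mean was -1.29 (camera adjusted p = 9.21e-17, and adjusted p = 0.179 with an estimated correlation). Matrix proteases and inhibitors had 13 of 26 fallen (15 adjusted over the list alone), with Ctsd (-1.61), Adam8 (-1.46) and Mmp14 (-1.37), and matrix assembly enzymes 8 of 16 (11 adjusted over the list alone), with the collagen chaperone Serpinh1 (-2.05), Adamts2 (-1.72), Plod3 (-0.93) and Plod2 (-0.91). Their means were -1.02 (1.41e-09) and -0.83 (1.38e-06), both at adjusted p = 0.179 with an estimated correlation. Cell cycle genes had 12 of 41 fallen (27 adjusted over the list alone), among them the mitotic kinase Cdk1 (-1.83), Cdc20, an activator of the anaphase-promoting complex (-1.73), cyclin Ccnb1 (-1.62) and cyclin Ccne1 (-0.80), at a mean of -1.001 (2.25e-11, and adjusted p = 0.52 with an estimated correlation). Coagulation and fibrinolysis had 5 of 16 fallen (8 adjusted over the list alone), with the urokinase receptor Plaur (-1.49), Plat (-1.20), F13a1 (-1.16) and Anxa2 (-1.03), at a mean of -0.36 (0.00955, and adjusted p = 0.179 with an estimated correlation). That mean was -0.55 (0.0038) without 4 months replicate 1. On that array 6 of the 16 genes lay more than 1 log2 above and 9 more than 1 log2 below the median of the other arrays. Members fallen over all probes in these 5 lists, in this order, were 29, 15, 12, 22 and 6 when it was left out.

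Macrophages and monocytes had 9 of 26 genes fallen (13 adjusted over the list alone), with Gpnmb (-2.0), Cd68 (-1.51), Fcgr3 (-1.36) and Csf1r (-1.35), at a mean of -0.77 (camera adjusted p = 2.56e-05, and adjusted p = 0.438 with an estimated correlation). Alternatively activated macrophages had 3 of 16 fallen (3 adjusted over the list alone), Spp1, Il4ra (-1.20) and Mgl2 (-0.75), at a mean of -0.65 (0.0471, and adjusted p = 0.52 with an estimated correlation). The p53 response list had 7 of 23 fallen (10 adjusted over the list alone), with Bax (-1.01), Aen (-0.64) and Sesn2 (-0.57), at a mean of -0.32 (0.0211, and adjusted p = 0.269 with an estimated correlation). Neutrophils had 1 of 13 fallen (1 adjusted over the list alone), Mmp8 (-1.68), and chemokines and cytokines 3 of 41 (3 adjusted over the list alone), Cxcl14 (-1.49), Cxcl16 (-1.15) and Ccl3 (-0.90). Their means were -0.27 (0.0471) and -0.39 (0.0398), with adjusted p = 0.583 and adjusted p = 0.636 with an estimated correlation. Members fallen over all probes in these 5 lists, in this order, were 10, 7, 11, 2 and 6 without 4 months replicate 1, while 3 p53 response genes and 1 neutrophil gene rose.

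A group of lists passed here with 4 months replicate 1 and not without it: alveolar type 2 cells (-0.95, 0.00529), contractile and fibroblast genes (-0.65, 0.0158), immediate early and heat shock genes (-0.46, 0.0144) and endothelial cells (-0.36, 0.0489). With an estimated correlation these had adjusted p = 0.583, 0.583, 0.52 and 0.722. Without that array they stood at -0.29 (0.243), -0.30 (0.243), -0.19 (0.304) and 0.02 (0.976). Conversely, complement (-0.74, 0.0139) and club and goblet cells (0.43, 0.0312) passed without it, with adjusted p = 0.749 for both with an estimated correlation; over all 18 arrays they stood at -0.53 (0.0607) and -0.13 (0.622), and complement passed there with the mean of all probes of a gene. T and NK cells passed with saline replicate 1 left out as well (0.26, 0.0356). Their adjusted p = 0.771 with an estimated correlation. The p53 response, neutrophil and chemokine lists also failed without it, at 0.0997, 0.304 and 0.304. Type 2 cells had 3 of 14 fallen (5 adjusted over the list alone), the surfactant protein Sftpb (-1.45), the phosphate transporter Slc34a2 (-1.10) and Ctsh (-0.78), and endothelial cells 2 of 19 (2 adjusted over the list alone), the tight junction gene Cldn5 (-1.26) and Plvap (-0.72). Contractile genes had 3 of 19 fallen (8 fallen and 1 risen adjusted over the list alone), Acta2, desmin Des (-1.18) and Cald1 (-0.98, its other probe of opposite sign), and immediate early genes 3 of 18 (4 fallen and 1 risen adjusted over the list alone), Atf3 (-1.12), Junb (-1.05) and Fos (at least 1.45-fold lower). Without that array 6 type 2 cell genes fell. Of the endothelial genes 2 fell and 2 rose, 6 contractile genes fell and 2 rose, and 3 immediate early genes fell and 1 rose.

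In lists that did not pass over all 18 arrays, Sfrp1 (-2.17), C1qa (-1.82), Tgfbi (-1.77), C3ar1 (-1.54), Sod3 (-1.53), C1qb (-1.21), C1qc (-1.17), Ltbp1 (-1.12, its other probe of opposite sign), Bhlhe40 (-0.94), Gsr (-0.92), Fst (-0.86), the hedgehog inhibitor Hhip (-0.73), Fzd2 (-0.62) and Xbp1 (-0.58) fell. Gsta4 (0.76) and Aox1 (0.80) rose, and Hlf was at least 1.23-fold higher. Of the probes called higher in the fibrotic stage than on saline, 326 were lower again in reversion (28.7 if the calls were independent), and 55 of those called lower were higher again (3.46 if independent). Both comparisons hold the same 6 fibrotic arrays with opposite sign, so these calls are not independent. Across probes the covariance, with the sign of the second turned, was 0.166, against 0.037 for simulated unchanged groups. With the fibrotic arrays divided, so that no array was in both, it was 0.154 for 1 month against saline and reversion against 2 months and 0.147 for 2 months against saline and reversion against 1 month, against 0 in simulation. In each division 29 probes were higher and then lower (1.85 and 1.0 if independent) and 3 lower and then higher (0.156 and 0.067 if independent).

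By limma, 1278 of 13724 probes were called between reversion and the fibrotic stage, 364 higher and 914 lower. The count was 3816 without 4 months replicate 1 (1800 higher, 2016 lower), and 4384 without saline replicate 1 as well. It was 591 without 1 month replicate 1, 698 without 1 month replicate 2, 589 without 2 months replicate 3, 676 without 3 months replicate 1 and 679 without 3 months replicate 2. Series B alone gave 2351 (919 higher, 1432 lower) and series A alone 2933, where the reversion side holds 4 months replicate 1 and 3 months replicate 1 only. The array series as a block gave 1408, the replicate block 1172 and only the compared groups in the fit 846.

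**Figure D4:**
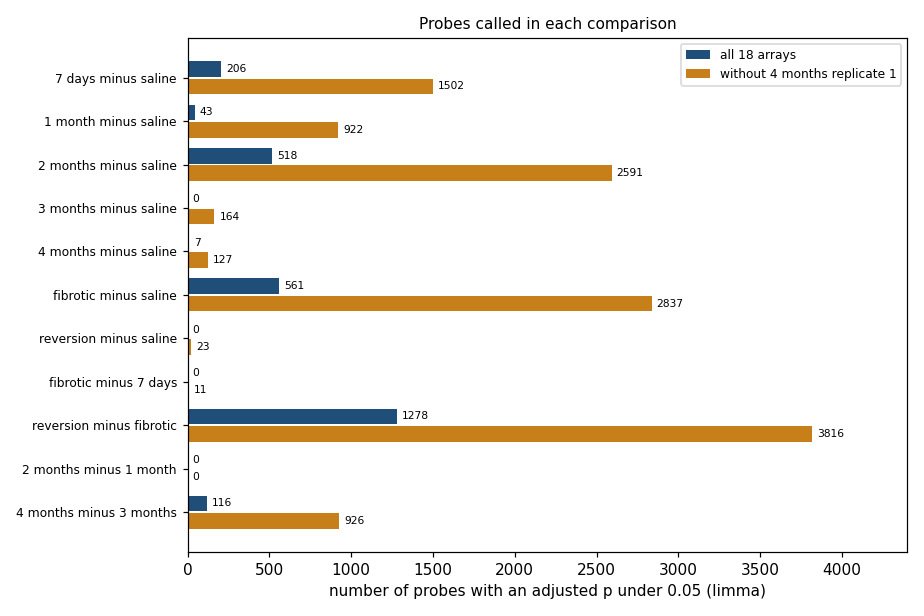
Number of probes called by limma (adjusted p under 0.05) in each of 11 comparisons, with all 18 arrays and without 4 months replicate 1. The count between reversion and fibrotic was 1278 and 3816, and that between reversion and saline 0 and 23.

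The comparison of 3 and 4 months with saline asked what remained changed. The genes with the smallest p, none of them called, were Sp5, a transcription factor of Wnt signalling (log2 1.44, adjusted p = 0.1), Antxr1 (-2.04, 0.1, with values on 2 of the 6 reversion arrays), the metabolic kinase Pdk4 (-0.90, 0.151), Pxmp2 (1.44, 0.167) and Cyp4a12b (-1.67, 0.167). Spp1 stood at 12.17 ± 1.52 (SD, n = 6) against 9.51 ± 1.56 (SD, n = 3), log2 2.66 (0.188), and passed without 4 months replicate 1 at 3.00 (0.028). Sp5 (1.52, 0.0252) and Pdk4 (-0.89, 0.0451) passed without that array too. Antxr1 and Pxmp2 could not be tested without it, since it held their only value at 4 months. The remaining looked-up genes did not pass: Mmp12 at 1.69 (0.463), Mmp19 at 0.82 (0.543), Cdkn1a at 0.76 (0.493), Timp1 at 0.57 (0.769), Tgfb1 at -0.32 (0.741), Tnc at -0.68 (0.707), Acta2 at -0.75 (0.65), Col1a1 at -0.76 (0.517), Col3a1 at -0.76 (0.657) and Ager at -1.36 (0.657). The Ager difference rested largely on 4 months replicate 1, where Ager stood at 5.91, against at least 12.06 on the other 17 arrays. Eln was not above background on any array of either group.

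Among the lists, with 0 members called over all probes in each, fat tissue (mean -1.68, camera adjusted p = 4.95e-07) and heart and skeletal muscle (-1.47, 2.56e-07) were lower than on saline, with 6 of 12 and 10 of 19 genes fallen adjusted over the list alone. The latter count was 0 of 19 without 4 months replicate 1, at a mean of -1.32 (3.61e-06). They had adjusted p = 0.146 and adjusted p = 0.692 with an estimated correlation. Higher lists were B and plasma cells (0.46, 0.00678), alternatively activated macrophages (0.52, 0.0339), macrophages and monocytes (0.25, 0.0149) and complement (0.24, 0.00652). With an estimated correlation these had adjusted p = 0.721, 0.692, 0.721 and 0.721. Without 4 months replicate 1 the B and plasma cell list stood at 0.67 (5.62e-06), and complement at 0.04 (0.217). With saline replicate 1 left out as well, only the B and plasma cell list passed among the higher ones, at 0.69 (2.51e-05), while alternatively activated macrophages stood at 0.29 (0.402) and macrophages and monocytes at 0.20 (0.249). With array series as a block only complement passed among them, and the B and plasma cell list stood at 0.23 (0.223). Adjusted over the list alone, 1 gene rose in the B and plasma cell list (7 without 4 months replicate 1), 1 rose in the alternatively activated and 1 fell in each of the macrophage and complement lists. The cell cycle list was lower at -0.81 (3.85e-12, and adjusted p = 0.692 with an estimated correlation), and stood at -0.02 (0.675) without 4 months replicate 1 and saline replicate 1. T and NK cells (-0.73, 0.00232), contractile and fibroblast genes (-0.57, 0.00652), immediate early and heat shock genes (-0.38, 0.00436), alveolar type 1 cells (-0.67, 0.0107), club and goblet cells (-0.81, 0.0473) and endothelial cells (-0.33, 0.0473) were lower. With an estimated correlation these had adjusted p = 0.692, 0.721, 0.692, 0.806, 0.721 and 0.806, and without 4 months replicate 1 only T and NK cells passed among them, at -0.54 (0.0138). With saline replicate 1 left out too, T and NK cells stood at -0.12 (0.327), while contractile and fibroblast genes (-0.28, 0.0201), immediate early and heat shock genes (-0.28, 0.0201) and alveolar type 1 cells (-0.32, 0.0185) passed. These 3 lists had adjusted p = 0.581, 0.581 and 0.807 with an estimated correlation without both, and the B and plasma cell list adjusted p = 0.383. Matrix proteases and inhibitors did not pass over all 18 arrays and were higher than on saline without 4 months replicate 1 (0.34, 0.0299, and adjusted p = 0.874 with an estimated correlation).

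By limma, 0 of 13696 probes were called between reversion and saline, with 1292 at an unadjusted p under 0.05. The count was 23 without 4 months replicate 1, 5 without saline replicate 1 as well, 36 without 3 months replicate 1, 1 without saline replicate 1, 2 without saline replicate 2, 1 without saline replicate 3 and 1 without 4 months replicate 2. The replicate block and the array series as a block each gave 0, and series A alone 2907, where reversion is 3 months replicate 1 and 4 months replicate 1. Series B holds no saline array.

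Taken alone, 3 months gave 0 called probes against saline (1289 at an unadjusted p under 0.05 by limma) and 4 months 7 (3 higher, 4 lower). Without 4 months replicate 1 these were 164 and 127, and 261 and 7 without saline replicate 1 as well. At 3 months the count was 24 without saline replicate 3 and 19 without 3 months replicate 1; at 4 months it was 12 without saline replicate 2, 11 without saline replicate 3, 11 without 4 months replicate 2 and 11 without 4 months replicate 3. The replicate block gave 0 and 4, the array series as a block 0 and 9, and series A alone 3 and 5568, the latter resting on 4 months replicate 1 alone. Between 4 and 3 months 116 probes were called (46 higher, 70 lower), 926 without 4 months replicate 1 (571 higher, 355 lower) and 1389 without saline replicate 1 as well. That count was 19 without 3 months replicate 1, 11 without 3 months replicate 2, 11 without 3 months replicate 3, 54 without 4 months replicate 2 and 177 without 4 months replicate 3. The replicate block gave 121, the array series as a block 211, series B alone 1253 (772 higher, 481 lower), series A alone 4058, a test of 3 months replicate 1 against 4 months replicate 1 with the spread of other groups, and only the compared groups in the fit 0.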

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

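All tests of the causes of a pattern in this part were chosen after the result had been seen, and the counts of other splits of the arrays were planned. Direct tests between times after bleomycin called 1278 probes between reversion and the fibrotic stage and 116 between 4 and 3 months, which are both of the reversion stage; the latter count was 0 by limma with only the compared groups in the fit. Between the fibrotic stage and 7 days limma called 0 (830 at an unadjusted p under 0.05).

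For the splits, the arrays of a comparison were regrouped in groups of the same sizes, with the arrays of the other groups left in the fit. Each stage counted as 1 group, so that real counts of stages can differ from those of the model with 6 group means. Between reversion and the fibrotic stage 553 probes were called, and the highest of the other splits gave 5. The real count was reached by 1 of 100 splits drawn from 462, the real one, which makes chance unlikely but cannot exclude it. In splits that mix the groups, a real difference adds to the spread and lowers the count. The highest other split put the 6 arrays of series B together; within series B the real comparison gave 2351. Between the fibrotic stage and saline, 1 of 84 splits, the real one, reached 668 (highest other 24), which makes chance unlikely without excluding it. Between reversion and saline the real count was 0, which all 84 splits reach whatever the data, so nothing follows from this number about chance. Of these splits 24 called probes, the highest 387 with 3 months replicates 2 and 3 and 4 months replicate 1 together, which points to a structure of the samples. Between the fibrotic stage and 7 days the real split gave 2, which 2 of 84 splits reached, the other with 105, and the model with 6 group means called 0. No conclusion on chance is drawn from so small a count, and a split with many times the real count again points to a structure of the samples. Comparisons of 3 with 3 arrays have 10 splits, too few for a share under 0.05. Real and highest other counts there were 206 and 0 at 7 days, 43 and 0 at 1 month, 518 and 0 at 2 months, 0 and 29 at 3 months, 7 and 52 at 4 months, 0 and 1 for 2 months against 1 month, and 116 and 1 for 4 against 3 months. As many probes as in the real split were reached by 1, 1, 1, 10, 2, 10 and 1 of these splits.

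4 months replicate 1 stood apart from the other 17 arrays: its correlation with any of them lay between 0.643 and 0.692, against 0.855 to 0.985 among the others, and Alb stood at 15.22 (at most 7.05 elsewhere), Apoa1 at 15.16 (7.52), Ahsg at 15.11 (8.5) and Sftpc at 6.96 (at least 14.97). A dim array as the whole cause is argued against by 1131 probes over 2-fold brighter than on every other array before scaling, against at most 229 on another array, and wrongly restored decimal points by 823 probes with settled decimals more than 1 log2 above all others, against at most 119, settled or not, on another. Both tests were chosen after a first test of the same explanation had missed its bound and left it undecided: 271 probes were above background on this array alone (highest other 130), and 76.4% of 1077 high probes had settled decimals. RNA of liver in place of lung is a candidate explanation: the median of 17 measured of 30 listed hepatocyte markers lay 7.375 above the other arrays (next array 0.324), 15 of them more than 1 log2 above all others, with the alveolar type 2 list at -5.004; 6 of the markers were above background on all other arrays, and 23.5% are in another list. Whether another organ was taken, tubes were exchanged or an outside sample was used stays open, and no biological explanation was tested.

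T cell precursor genes were high on saline replicate 1: Rag1, the recombinase of developing lymphocytes, stood at 10.61 (others at most 7.42), Cd8b1 at 13.04 (7.56), Cd8a at 12.74 (7.89), Tcf7 at 13.41 (9.31) and Lck at 13.83 (10.92). Mature lymphocytes of blood or a lymph node as the source are argued against by the B and plasma cell list, at -0.109 relative to the other arrays. RNA of thymus, which lies next to the lungs and holds dividing T cell precursors, is a candidate source: the thymus and lymph node list lay 2.89 above the other arrays (next array 0.46) and the cell cycle list 1.43. Of the 7 measured genes of the thymus and lymph node list, 4 lay more than 1 log2 above all others, 3 were above background on all other arrays and 2 are also in the T and NK cell list. No biological explanation was tested, and how much thymus RNA the array would hold was not estimated.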

How the results depend on the processing

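Settings chosen after seeing the data were the offset of 10, open decimals set to missing, the fits without 4 months replicate 1 or without that array and saline replicate 1, and all list tests without an array; the others were planned. Without background correction 20 probes were called at 1 month against saline and 1 between the fibrotic stage and 7 days. Median scaling gave 336 at 7 days, 100 at 1 month (90 higher and 10 lower, against 34 and 9 with quantile normalization), 6 at 3 months, 2 at 4 months, 4 between the fibrotic stage and 7 days and 76 between 4 and 3 months; it moved the median of all genes by less than 0.1. No filter gave 19 at 4 months and 3 between reversion and saline. With only the compared groups in the fit, counts were 173 at 1 month, 0 at 4 months, 1772 in the fibrotic comparison, 9 between the fibrotic stage and 7 days, 846 between reversion and the fibrotic stage and 0 between 4 and 3 months. Trend and robust variance gave 17 at 1 month and 1 between the fibrotic stage and 7 days. The replicate block gave 4 at 4 months, although the replicate numbers do not pair the arrays (16 of 45 same-number pairs correlated over 0.1). Array series as a block gave 24 at 1 month and 211 between 4 and 3 months. Series A alone gave 792 at 7 days, 196 at 1 month, 3 at 3 months, 5568 at 4 months, 1244 in the fibrotic comparison, 2907 between reversion and saline, 1 between the fibrotic stage and 7 days, 2933 between reversion and the fibrotic stage and 4058 between 4 and 3 months, the last with 1 array on each side. Series B alone gave 2351 between reversion and the fibrotic stage, 2 between 2 months and 1 month (1 array on each side) and 1253 between 4 and 3 months. The authors' values gave 5 at 3 months, 4 at 4 months, 6 between reversion and saline, 3 between the fibrotic stage and 7 days and 49 between 4 and 3 months. An offset of 10 gave 23 at 1 month and 1 between the fibrotic stage and 7 days, and open decimals set to missing gave 132 at 7 days, 17 at 1 month, 320 at 2 months, 3 at 3 months, 55 at 4 months, 4 between reversion and saline and 183 between 4 and 3 months. Lists called were 16 at 7 days, 14 in the fibrotic comparison, 13 between reversion and saline, 5 between the fibrotic stage and 7 days and 14 between reversion and the fibrotic stage; with an estimated correlation they were 0 in all 5, also without 4 months replicate 1 and without both that array and saline replicate 1, and with fry 9, 12, 1, 0 and 10. Fits without an array, which include those without 4 months replicate 1 and without that array and saline replicate 1, gave counts from 8 to 2104 at 7 days, 0 to 1264 at 1 month, 105 to 3272 at 2 months, 0 to 261 at 3 months, 5 to 127 at 4 months, 114 to 3218 in the fibrotic comparison, 0 to 36 between reversion and saline, 0 to 11 between the fibrotic stage and 7 days, 589 to 4384 between reversion and the fibrotic stage, 0 throughout between 2 months and 1 month and 11 to 1389 between 4 and 3 months. Lists were refitted only without 4 months replicate 1, without saline replicate 1 and without both; lists called ranged from 13 to 16, 11 to 13, 6 to 9, 5 to 7 and 9 to 10 in the same order as above. The endothelial cell list turned between reversion and saline from -0.333 to 0.05 without 4 months replicate 1 (-0.46 without saline replicate 1), and between reversion and the fibrotic stage from -0.361 to 0.022 without both arrays (-0.361 without saline replicate 1). For named genes, 2541 of 2819 comparisons with a setting stayed on the same side of the threshold, 251 no longer passed, 27 newly passed and 0 turned among those called in either fit; with arrays left out these were 2042, 471, 28 and 0 of 2541. In each of these sums 8 values that never passed changed sign. Fewer arrays or genes enter some of these fits; the cause of the other changes was not tested. Where a left-out array leaves a group with 2 or fewer, the spread comes from all groups. Signal limits the lists too: 6075 of 19799 probes were too dim to keep, and probes near background or saturated give compressed differences.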

Other observations

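All values in this part were noticed after the data were seen, and no cause was tested. Ighg1, an antibody heavy chain, stood at 6.60 ± 0.66 (SD, n = 3) on saline, lay below background on all 3 arrays at 7 days, and stood at 11.31 ± 1.29 at 1 month, 11.63 ± 0.46 at 2 months, 11.32 ± 0.95 at 3 months and 8.13 ± 2.55 at 4 months, where it was above background on 2 of 3 arrays. The B and plasma cell list was higher in reversion than on saline by a mean of 0.46 with all 18 arrays (camera, adjusted p = 0.00678) and 0.69 (adjusted p = 2.51e-05, and adjusted p = 0.383 with an estimated correlation) with 4 months replicate 1 and saline replicate 1 left out. Over all 18 arrays it did not pass with an estimated correlation (adjusted p = 0.721), with fry (adjusted p = 0.487) or with array series as a block (mean 0.23, adjusted p = 0.223). The block fit includes 4 months replicate 1, the only series A array at 4 months. This list stood there at -0.75 relative to the other arrays, and the block was not fitted without that array.

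Skeletal muscle genes varied between arrays of a group. Acta1, the actin of skeletal muscle, stood at 12.73, 12.49 and 6.95 on saline, 11.41 on 7 days replicate 1 and 13.36 on 3 months replicate 1, and at no more than 6.82 on the remaining arrays. The oxygen carrier Mb stood at 12.06, 12.52 and 11.38 on saline, 13.51 on 3 months replicate 1 and no more than 10.30 elsewhere. The interferon list was highest on 7 days replicate 3, at 1.46 above the other arrays with 21 of 26 genes more than 1 log2 higher, and next on 3 months replicate 2, at 0.62.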
